A study of Caenorhabditis elegans with 2 samples.

How the data were processed

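The series measured where an eGFP-tagged W03F9.2 protein sits on the genome of Caenorhabditis elegans by ChIP-seq, in which protein-bound chromatin is immunoprecipitated and its DNA is sequenced. Per the labels, whole worms of strain OP215 at the L4 to young adult stage were used, with both sexes pooled, in 2 biological replicates that form 1 group. The strain carries a mutant unc-119 allele and an integrated transgene with the tagged gene. The labels' antibody field names W03F9.2 while their description names the eGFP fusion, so the epitope that was precipitated is not settled by the labels.

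Peak lists of 4 kinds were deposited for each of the genome builds ce10 and ce11: a list of peaks and background for each replicate, the same kind of list for both replicates together (the pooled list), and the optimal set kept by the authors' IDR step, which sets a threshold from how reproducibly peaks rank. Per the files' accompanying notes, the peaks were called against a control alignment. The aligner, the caller and their settings are not given in the sources used here. The signal of each peak is the authors' own value as deposited, in the units of their caller, and it was used here to describe and rank peaks within a list. The deposited −log10 q-value takes a single value throughout the optimal set and was used only to check the lists. Every list of a replicate and every pooled list held 30000 entries, and the ce11 optimal set held 2409. These 2409 peaks were exactly the 2409 of highest signal in the pooled list. The reported summit lay at the middle of the peak in 87.9% of optimal-set peaks, so summit positions are approximate. The control library's own signal was not analysed here, and read depths per sample are unknown, so the intervals printed for shares cover only counting error over peaks or genes.

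All main results used the ce11 lists, whose coordinates fit within the chromosomes of the WBcel235 assembly. Gene models came from Ensembl release 115. The ce10 lists were compared only with each other. Coordinates are 1-based. A promoter was defined as the span from 1000 bp upstream to 200 bp downstream of the annotated start of a protein-coding gene, and a summit counted for every gene whose promoter held it. Chance was estimated from 1000 circular shifts of the peaks along each chromosome, which give a smallest two-sided permutation p of 0.001998 and a smallest one-sided p of 0.000999. Replicates were compared by the share of optimal-set peaks overlapped by at least 1 bp by the 2409 highest-signal entries of each replicate, and by the correlation of log2 signal over matched peaks, with a 95% interval from 1000 bootstrap draws of peaks. Signal inside and outside promoters was compared by a two-sided permutation test with 100000 resamples. Fisher's exact test, two-sided, compared the optimal set with the 10000 lowest-ranked entries of the pooled list, and each of 30 gene lists with all other protein-coding genes. Chromosome shares were compared with shares of protein-coding genes by exact binomial tests. Each 6-mer, both strands read as one, was tested by an exact McNemar test of its presence within 50 bp of the summit against the flanks from 200 to 250 bp away. Benjamini-Hochberg adjustment was applied within each family of classes, chromosomes, lists or 6-mers, with a threshold of 0.05. Where a list had no member with a summit, the share it allows is 3 divided by the number of members, an approximate one-sided 95% limit, while the figure of the lists shows exact two-sided intervals.

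The tests, the gene lists and the rule for named genes were fixed before the data were examined. Named genes are W03F9.2, the genes at the 20 optimal-set peaks of highest signal, the 4 members with the highest promoter signal of each list past the threshold, and at most 2 members of each other list. Other genes are named only as chosen after their values were seen. The flanks of the 6-mer test have the same total length as the summit window to within 1 bp, but hold slightly fewer 6-mer positions because they are split in 2. This was noticed after the counts were seen. The test was kept as fixed, and a version with equal positions was added as an alternative.

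The steps were tested on simulated data. With summits planted at 3 of the 30 gene lists over 19985 protein-coding genes, all 3 lists were called, together with 1 other list, and none of 40 sets of random summits gave a called list. The random summits were spread evenly over the genome, while most real summits lie in promoters. The 40 sets therefore do not show how often lists are falsely called when summits gather at promoters. Of the same 40 sets, 1 had a promoter share with a permutation p under 0.05. A 6-mer planted in 200 of 1000 simulated windows ranked first, with 8 6-mers called in all. Summits planted at 60 tRNA genes gave an adjusted permutation p of 0.00999 for that class. With 1000 shifts, a value this low arises only if at least 1 class without planted summits was called too. None of 10 random sets gave a called class. Alternatives covered a more stringent set of the 1204 peaks of highest signal, the top peaks of each replicate alone, merged peaks, narrower and wider promoters, other backgrounds and other matching rules. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.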

Results

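The data comprised peak lists from ChIP-seq of eGFP-tagged W03F9.2 in whole L4 and young adult C. elegans, with 2 biological replicates in 1 group. W03F9.2 is annotated as a protein with a C2H2-type domain, a zinc finger fold found in many DNA-binding proteins. The optimal set held 2409 peaks in ce11, with a median width of 350 bp. Their signal ranged from 48.5 to 10729 with a median of 69.8. No untagged or untreated group is among the samples, so comparisons were made between replicates, between places in the genome and between gene groups.

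The first comparison asked how far the replicates agreed. The strongest nuclear peak, upstream of sqd-1 on chromosome IV, ranked 4 in both replicate lists, with signals of 934 in replicate 1 and 1556 in replicate 2. The peak at egl-30, which encodes a G protein alpha subunit, ranked 8 in replicate 1 and 6 in replicate 2. Peaks at the ribosomal protein genes rpl-20, rpl-3 and rpl-15 ranked between 17 and 25 in both lists. Of the 2409 optimal-set peaks, 1801 (74.8%) were overlapped by the top entries of replicate 1 and 2042 (84.8%) by those of replicate 2. Both replicates overlapped 1512 peaks (62.8%), against 1.68% by circular shifts (one-sided permutation p = 0.000999, the smallest these shifts can give). The optimal set is the top of the list pooled from both replicates, so this overlap is not independent of them. Between the replicates alone, 1563 of the 2409 top entries of replicate 1 (64.9%) were overlapped by those of replicate 2, against 2.38% by shifts (permutation p = 0.000999). Over the 2378 peaks matched in both full lists, log2 signal had a Pearson r of 0.67 (95% bootstrap interval 0.62 to 0.71) and a Spearman rho of 0.49, across peaks that are not independent replicates. Signal was higher in replicate 2 by a median of 0.66 on the log2 scale, and the log2 ratio had an SD of 0.66 across peaks. Without the 20 mitochondrial peaks, an alternative chosen after seeing the data, r fell to 0.57, and in a more stringent set, the 1204 peaks of highest signal, it was 0.74.

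**Figure D1:**
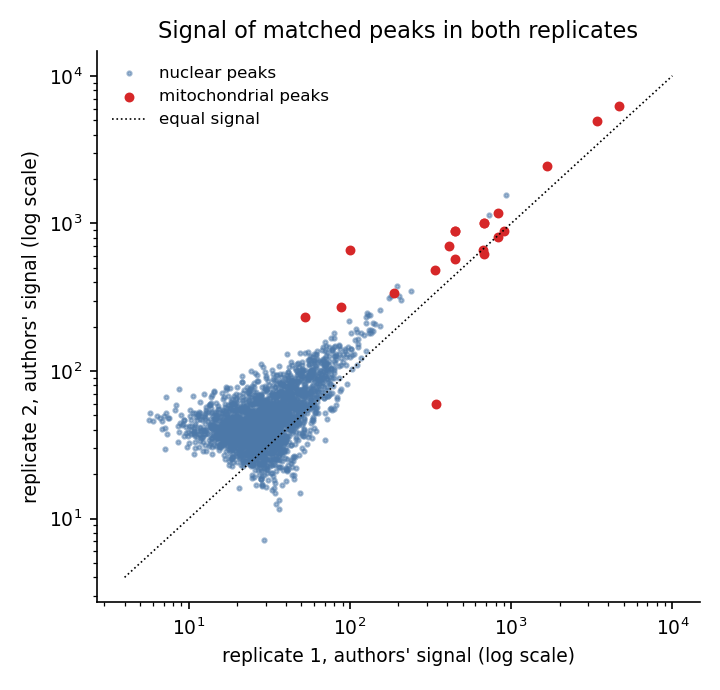
Authors' signal of each of the 2378 matched optimal-set peaks in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes in the caller's units, with nuclear peaks in blue and mitochondrial peaks in red. Most points lie above the dotted line of equal signal, and the mitochondrial peaks extend to 4647 and 6215.

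The second comparison asked where summits lay relative to genes. Promoters of protein-coding genes held 1679 summits, 69.7% of the set (exact 95% interval 67.8 to 71.5), against 21.7% by circular shifts (two-sided permutation p = 0.001998, the smallest these shifts can give). Exons outside promoters held 1.58% against 23.3% by shifts, introns 12.6% against 31.1%, and intergenic sequence 16.1% against 23.8%, each with the same permutation p of 0.001998. Promoter summits lay at a median of 189 bp upstream of the nearest start, a position of -189 with quartiles at -314 and -99.5. Of the promoter summits, 669 (39.8%) fell in the promoters of 2 or more genes, and 629 (37.5%) in those of genes on both strands. In all, 2331 of 19985 protein-coding genes (11.7%) had a promoter summit.

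**Figure D2:**
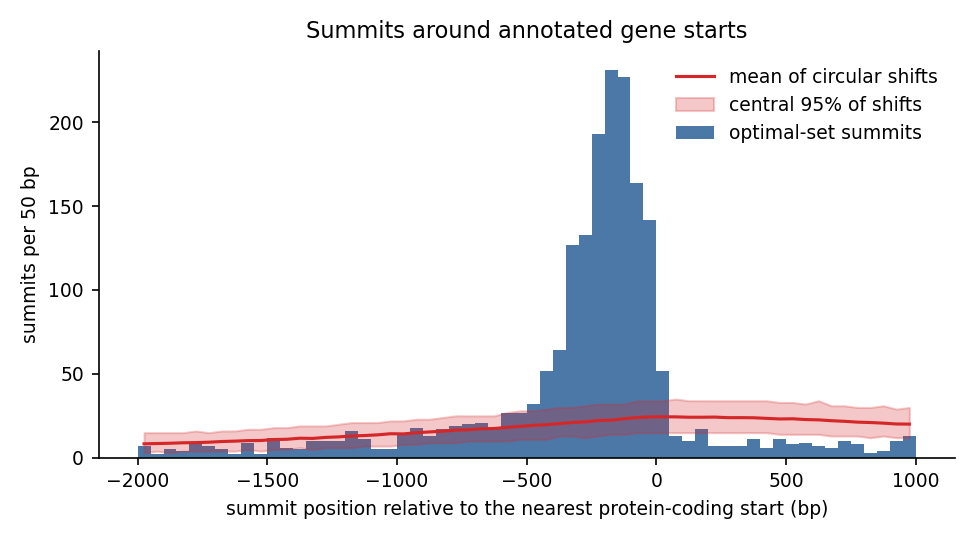
Number of optimal-set summits per 50 bp (bars) by position relative to the nearest protein-coding start in bp, negative values upstream, with the mean (line) and central 95% (band) of 1000 circular shifts. Summits pile up just upstream of starts, around the median position of -189 bp, and fall below the shifts inside genes.

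Promoter position went with signal. The strongest 3000 entries of the pooled list had 65.9% of summits in promoters (exact 95% interval 64.2 to 67.6), the next 3000 had 42.3%, and the weakest 3000 had 20.4%. Against the 20.1% of the 10000 lowest-ranked entries, the optimal set had an odds ratio of 9.15 by Fisher's exact test, with a two-sided p below 1e-300, and of 15.8 in the more stringent peak set and 6.06 with wide promoters. Within the optimal set, the median signal was 76.3 at promoters and 62.3 elsewhere, a log2 difference of 0.29 (permutation p = 2e-05, the smallest these resamples can give).

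The strongest peaks were mitochondrial. Of the 20 peaks of highest signal, 15 lay on the mitochondrial genome, led by a peak at 4598 to 4942 with a signal of 10729. Its summit lay 256 bp downstream of the nearest protein-coding start, that of another gene than COX3. It counted for COX3, a subunit of cytochrome c oxidase, because it fell within that gene's promoter window. In all, 20 peaks covered 52.1% of the 13794 bp of that genome, with a median signal of 1055 against 69.4 for nuclear peaks. Promoter windows overlap genes there, since mitochondrial genes are closely packed. How many copies of this genome the animals carry was not measured, so its signal does not separate binding from template. The 5 nuclear peaks among the top 20 lay at sqd-1 on chromosome IV (6323623 to 6324137, signal 2453, summit 302 bp upstream of the start, at -302), egl-30 and C53H9.4 on I (1835406 to 1835818, 1855), rpl-20 and Y17G9B.5 on IV (4749920 to 4750227, 591), him-19 on I (894979 to 895274, 543) and cdc-48.1 on II (10563446 to 10563701, 524). cdc-48.1 encodes an AAA ATPase that works with the ubiquitin system.

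Shares of genes with a promoter summit differed widely between the gene lists. A summit can lie in the promoters of several genes, and such sharing is named below only in part. Ribosomal protein genes had a promoter summit in 68 of 81 cases (84.0%), proteasome genes in 25 of 33 (75.8%), translation factors in 28 of 45 (62.2%), the respiratory chain in 27 of 46 (58.7%) and splicing factors in 25 of 44 (56.8%). Of the lists past the threshold, the lowest shares were those of major sperm proteins at 0 of 43, chemoreceptors at 10 of 1364 (0.73%) and homeobox genes at 1 of 96 (1.04%). By Fisher's exact test with Benjamini-Hochberg adjustment, 11 of the 30 lists had summits more often than other genes, 10 less often, and 9 did not pass the threshold. With each summit counted only for the nearest start, the shares fell to 48.1% of ribosomal proteins, 54.5% of the proteasome, 42.2% of translation factors, 34.8% of the respiratory chain, 34.1% of splicing factors and 24.6% of chaperones, and these calls were kept. Against genes with any pooled-list entry in the promoter, the odds ratios of several lists were closer to 1 than among all genes. They were 18.9 for ribosomal proteins, 12.3 for the proteasome, 6.89 for translation factors, 5.54 for the respiratory chain, 5.12 for splicing factors and 0.207 for chemoreceptors, all still past the threshold. Those of nuclear hormone receptors (0.304 against 0.374), detoxification enzymes (0.302 against 0.334) and neuronal and synaptic genes (0.187 against 0.219) were further from 1.

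Among ribosomal proteins, the strongest promoter peaks were at rpl-20 (signal 591), rpl-3 (521), rpl-15 (488) and rpl-35 (369), and the list had an odds ratio of 40.8 (adjusted exact p = 1.76e-49). Translation factors had an odds ratio of 12.6 (adjusted exact p = 7.17e-15), led by ifet-1 (319), eif-3.C (283), eef-1A.1 (229) and eef-1G (221). The ifet-1 summit also lies in the promoter of rps-1, and the eef-1A.1 summit in that of rfc-4, a replication factor C subunit. Proteasome genes had an odds ratio of 23.9 (adjusted exact p = 2.26e-16), with rpn-3 (204), rpn-9 (180), rpt-2 (144) and pas-4 (135) in front. Each of these proteasome summits is shared with another gene, that of rpn-3 with hsp-110, a chaperone gene. Respiratory chain genes had an odds ratio of 10.9 (adjusted exact p = 1.23e-13), with signals of 374 at cox-5A, 225 at atp-3, 219 at atp-1 and 205 at cox-5B.

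Splicing factors had an odds ratio of 10.1 (adjusted exact p = 2.70e-12), and the SR protein genes rsp-1 and rsp-2 shared 1 summit with a signal of 207, followed by prp-40 (181) and prp-8 (154). Chaperones had summits in 30 of 65 cases (46.2%, odds ratio 6.56, adjusted exact p = 1.55e-11), among them dnj-9 (225), the chaperonin subunits cct-8 (210) and cct-1 (194), and hsp-110 (204). Vacuolar ATPase genes had them in 10 of 21 (47.6%, odds ratio 6.91, adjusted exact p = 0.00011), with vha-8 (156), vha-1 (127), vha-12 (107) and vha-15 (101) highest. Cell cycle and replication genes had them in 27 of 72 (37.5%, odds ratio 4.59, adjusted exact p = 3.95e-08), with cdc-48.1 (524), rfc-4 (229), pcn-1 (176), which encodes the replication clamp PCNA, and cdc-6 (167).

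Chromatin regulators had summits in 39 of 116 cases (33.6%, odds ratio 3.88, adjusted exact p = 1.26e-09). The strongest were at set-16 (282), an H3K4 methyltransferase gene, and at lin-54 (263), lin-53 (231) and lin-9 (221), whose products belong to the DRM complex. The lin-54 summit is shared with rpl-12. Argonautes and small RNA genes had them in 19 of 61 (31.1%, odds ratio 3.45, adjusted exact p = 1e-04), with ekl-4 (329), mut-15 (144), rde-4 (113) and rde-10 (107). Each of these summits is shared, with rps-20 at ekl-4, fib-1 at mut-15, cox-14 at rde-4 and rnp-6 at rde-10. Germline genes had them in 21 of 73 (28.8%, odds ratio 3.08, adjusted exact p = 0.000129), with ifet-1 (319), egg-5 (216), cgh-1 (123.2) and nos-3 (121). Counting each summit only for the nearest start ended the call for Argonautes and small RNA genes (14.8%, adjusted exact p = 0.134), and taking the more stringent peak set of highest signal ended it for germline genes (8.22%, adjusted exact p = 0.736). Against genes with any pooled-list entry in the promoter, the vacuolar ATPase (52.6%, adjusted exact p = 0.065) and germline genes (41.2%, adjusted exact p = 0.1) also lost the call.

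**Figure D3:**
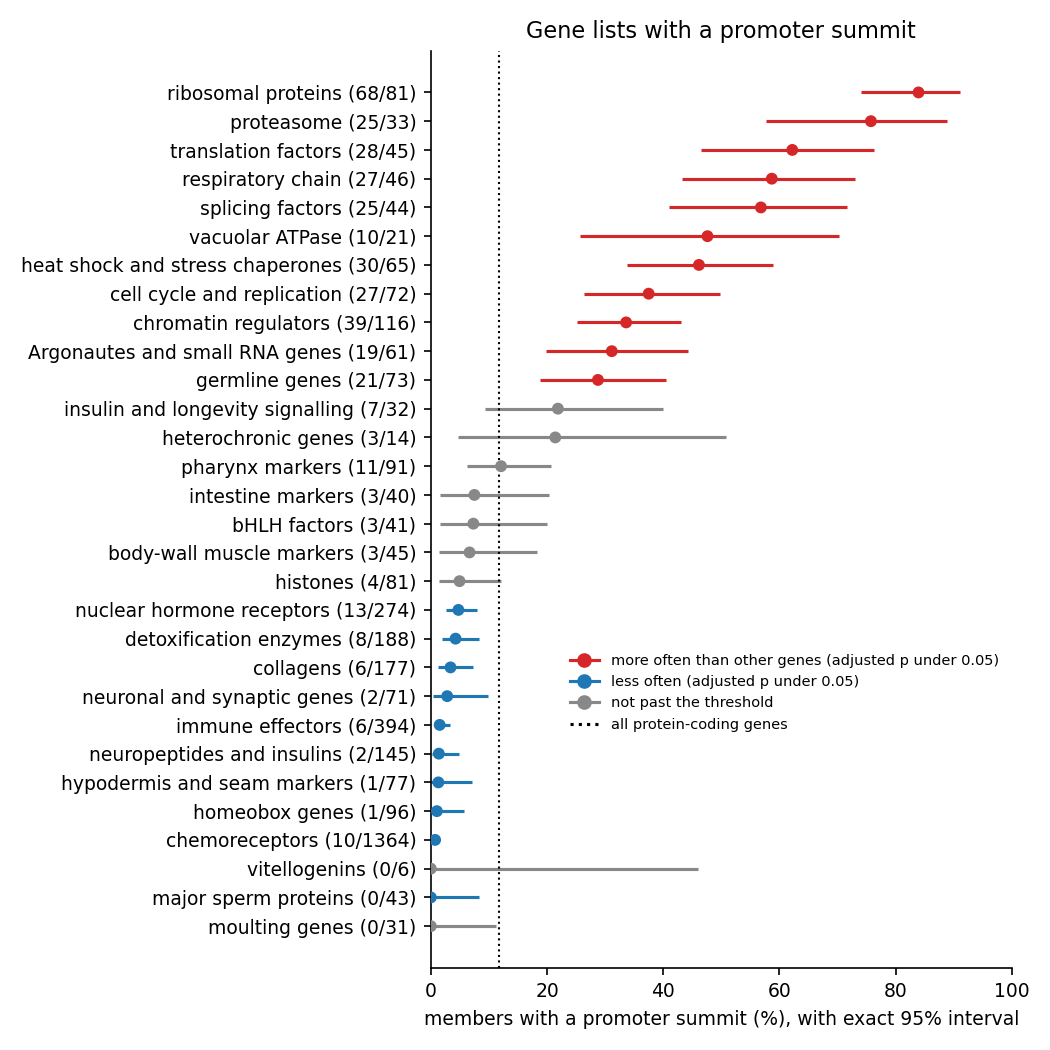
Percent of the members of each of the 30 gene lists with a promoter summit (points) and exact 95% binomial interval (lines), with the counts beside each name. Ribosomal proteins stand highest at 84.0% and chemoreceptors are at 0.73%, against 11.7% of all protein-coding genes (dotted line).

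Among the lists with fewer summits than other genes, chemoreceptors had an odds ratio of 0.0519 (adjusted exact p = 5.61e-59), and the promoter peak of sri-5 (signal 159) is shared with rsr-1. Immune effectors (odds ratio 0.115, adjusted exact p = 1.21e-13) had signals of 99.5 at fipr-17, 65.1 at clec-126, 59.0 at pals-32 and 58.4 at dod-21. Neuropeptides and insulins had 2 of 145 (1.38%, adjusted exact p = 1.59e-05), ins-39 (201) and nlp-4 (129). Nuclear hormone receptors had 13 of 274 (4.74%, adjusted exact p = 0.000184), led by nhr-142 (141), nhr-256 (107), nhr-47 (98.8) and nhr-49 (82.6). Collagens had 6 of 177 (3.39%, adjusted exact p = 0.000259), led by col-38 (218), whose summit is shared with rpl-5, and bli-6 (153), col-71 (95.3) and col-63 (80.0). Homeobox genes had 1 (adjusted exact p = 0.000296), ceh-38 (135). Detoxification enzymes had 8 of 188 (4.26%, adjusted exact p = 0.000928), led by gst-27 (101), gst-43 (81.6), gst-1 (63.3) and cyp-43A1 (61.8). Hypodermis and seam markers had 1 of 77 (1.30%, adjusted exact p = 0.00298), grl-26 (67.6), and neuronal and synaptic genes 2 of 71 (2.82%, adjusted exact p = 0.0211), snb-1 (97.1) and ehs-1 (79.5). Major sperm proteins had 0 of 43 (adjusted exact p = 0.0116), which allows a share of up to 6.98%. These are comparisons with other genes: against circular shifts, which put a summit at 2.27% of chemoreceptors and at similar shares of the others, only chemoreceptors of these 10 lists passed the threshold (adjusted permutation p = 0.00428), while collagens, nuclear hormone receptors (4.74% against 2.32%) and detoxification enzymes turned higher than chance without passing. Neuronal and synaptic genes lost the call without replicate 1 (4.23%, adjusted exact p = 0.0608), and in the more stringent set they (adjusted exact p = 0.329) and the major sperm proteins (0.114) did not pass. Neither passed with each summit counted only for the nearest start (adjusted exact p = 0.171 and 0.0742), nor did neuronal and synaptic genes with wide promoters (7.04%, adjusted exact p = 0.118). Against genes with any pooled-list entry, only 14 hypodermis and seam markers (7.14%, odds ratio 0.187, adjusted exact p = 0.121) and 2 major sperm protein genes were left, too few major sperm proteins to pass at any share.

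The 9 other lists did not pass the threshold. Histones had 4 of 81 (4.94%, adjusted exact p = 0.074), among them his-37 (signal 237) and htz-1 (208). Moulting genes had 0 of 31 (adjusted exact p = 0.0601), which allows up to 9.68%, and vitellogenins 0 of 6 (adjusted exact p = 1), which allows up to 50%. Insulin and longevity signalling had 7 of 32 (21.9%, adjusted exact p = 0.113), with rict-1 (113) and akt-2 (100.5). Heterochronic genes had 3 of 14 (21.4%, adjusted exact p = 0.262), with puf-9 (114) and lin-28 (72.2). Pharynx markers had 11 of 91 (12.1%, adjusted exact p = 0.9), with pqn-59 (157) and pqn-41 (122.7), which entered through the pqn family, named for glutamine- and asparagine-rich proteins and not for the pharynx. Intestine markers had 3 of 40 (7.50%), with lbp-6 (68.8) and dpf-3 (51.0), and bHLH factors had 3 of 41 (7.32%), with hlh-11 (123.02) and aha-1 (59.4), both at an adjusted exact p of 0.667. Body-wall muscle markers had 3 of 45 (6.67%, adjusted exact p = 0.555), with act-2 (108) and unc-112 (102). Against circular shifts, pharynx markers and insulin and longevity signalling (both adjusted permutation p = 0.00428) and heterochronic genes (0.012) had more summits than chance. With wide promoters, moulting genes had fewer (0%, adjusted exact p = 0.0158) and insulin and longevity signalling more (31.2%, 0.0269) than other genes.

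Noncoding genes of several classes had summits nearby more often than by circular shifts. These shifts take no account of protein-coding promoters, where most summits lie. Closeness to such promoters was therefore not separated from closeness to noncoding genes in these folds. Within 500 bp, snoRNA genes had 87 summits against 9.50 by shifts (9.16-fold), snRNA genes 20 against 3.16 (6.34-fold), tRNA genes 142 against 26.4 (5.38-fold, but 2.45-fold in the more stringent peak set and 10.1-fold without mitochondrial peaks, the latter chosen after seeing the data), miRNA genes 17 against 5.77 (2.95-fold) and the class annotated as ncRNA 361 against 151 (2.40-fold). The lincRNA class had 20 against 10.2 (1.95-fold, adjusted permutation p = 0.0325), a call that ended within 200 bp (adjusted permutation p = 0.0699) and in the more stringent peak set (adjusted permutation p = 0.566). Fewer summits lay near piRNA genes (51 against 110, 0.463-fold) and pseudogenes (35 against 113, 0.310-fold). Within 200 bp the fold was 15.8 for snoRNA, 11.6 for snRNA, 9.61 for tRNA, 3.92 for ncRNA, 0.295 for piRNA and 0.159 for pseudogenes, further from 1, and 2.59 for miRNA, 1.84 for lincRNA and 1.58 for antisense RNA, closer to it. Within 500 bp the adjusted permutation p was 0.00285 for each of snoRNA, snRNA, tRNA, miRNA, ncRNA, piRNA and pseudogenes. The rRNA class (7 against 5.99, adjusted permutation p = 0.725) and antisense RNA (9 against 4.55, adjusted permutation p = 0.104) did not pass the threshold. Antisense RNA passed without replicate 1 (adjusted permutation p = 0.0466) and without replicate 2 (0.0275), and miRNA genes lost the call within 200 bp (adjusted permutation p = 0.0699).

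Chromosomes I and III held more summits than their share of protein-coding genes. Chromosome I had 20.4% of summits against 14.4% of genes (adjusted exact p = 3.22e-15 by the exact binomial test) and III had 19.97% against 13.2% (adjusted exact p = 9.96e-20). Chromosome V, which is rich in chemoreceptor genes, had 14.4% against 24.99% (adjusted exact p = 4.17e-36), and the mitochondrial genome had 0.83% against 0.06% (adjusted exact p = 3.64e-16). Shares of genes take no account of the number of copies of the mitochondrial genome, so this excess does not by itself show binding there. Chromosome II had 15.4% against 17.3% (adjusted exact p = 0.0213), a call lost in the more stringent peak set (adjusted exact p = 0.243) and without replicate 1 (0.0879), and turned to 1.01-fold against chromosome length (0.821), while IV (16.4% against 16.4%, adjusted exact p = 0.956) and X (12.7% against 13.7%, adjusted exact p = 0.18) did not pass. On X, 145 of 305 summits (47.5%) lay in promoters, against 1518 of 2084 (72.8%) on the autosomes together (Fisher's exact test chosen after seeing the data, odds ratio 0.338, p = 6.32e-18). Against chromosome length, X did pass, with fewer summits (0.717-fold, adjusted exact p = 3.08e-11), as it did in the more stringent set against genes (0.808-fold, adjusted exact p = 0.0101).

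Sequences rich in C and G marked the summits. The 6-mer ACGCGC occurred within 50 bp of 332 of 2408 summits (13.8%) and in the flanks of 35 (1.45%), with an adjusted p of 1.89e-59 by the exact McNemar test. A second family read ACGCAG (15.3% against 2.41%), GACGCA (15.3% against 2.62%) and AGACGC (13.4% against 2.33%), overlapping words of AGACGCAG, which occurred at 8.76% of summits and 0.997% of flanks. GAGAGA was at 21.6% against 7.18%. Of 2080 6-mers, 630 were more frequent at summits and 435 less frequent, and A and T words such as AAAAAT (34.5% against 53.7%) led the latter. Mean GC content was 43.9% around summits and 34.7% in the flanks, so many of these words are not independent of base content.

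The region of W03F9.2 itself carried a cluster of peaks. The gene lies on chromosome V at 127000 to 128034 on the minus strand. A peak at 128022 to 128173 (signal 174, summit 63 bp upstream, at -63) sat at its start, in the promoter it shares with the divergent gene sftb-2. The strongest peak of the region, at 126642 to 126901, had a signal of 399 and ranked 24 in the optimal set. Its summit lay 59 bp upstream of W03F9.1, at -59, just past the 3′ end of W03F9.2. Within 20 kb there were 8 optimal-set peaks, and the pooled list had 38 entries there with a median signal of 24.7, against 15.8 over the rest of chromosome V. The strain carries an integrated transgene of this gene, in a copy number the labels do not give. At unc-119, which is mutant in the strain, 1 optimal-set peak lay within 20 kb, with a signal of 63.5 and rank 1495.

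**Figure D4:**
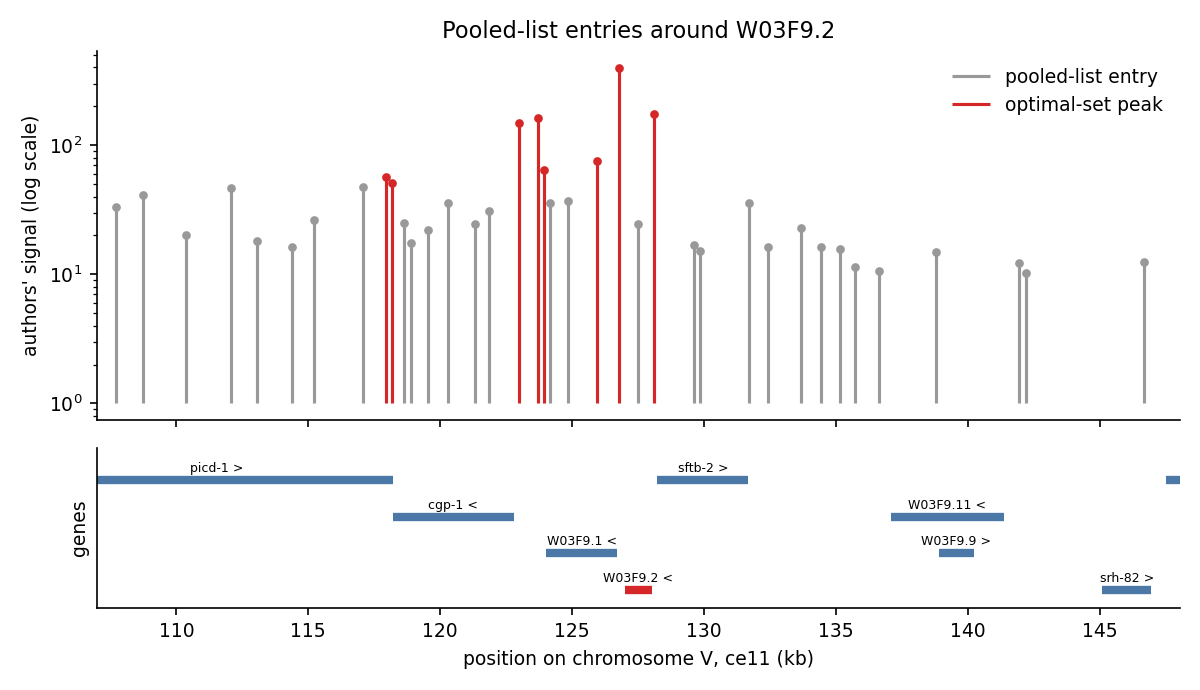
Authors' signal (log axis, caller's units) of the 38 pooled-list entries within 20 kb of W03F9.2 on chromosome V of ce11, by summit position in kb, with the 8 optimal-set peaks in red and protein-coding genes drawn to scale (arrowheads give the strand). The peak of 399 stands between W03F9.1 and W03F9.2, and no optimal-set peak lies to the right of the peak at the start of W03F9.2.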

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

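Alternatives without mitochondrial peaks, those of the 6-mer test with low-ranked entries or equal positions, and the replicate lists and merged peaks at W03F9.2, were chosen after seeing the data. No paired analysis was possible because the samples form 1 group. Promoter share (65.8% to 70.0% without replicate 2 or 1), its odds ratio against low-ranked entries, the promoter signal difference and replicate overlap kept direction and side of the threshold throughout. Pearson r moved from 0.67 to 0.74 in the 1204 peaks of highest signal and to 0.57 without mitochondrial peaks; the cause was not tested. With circular shifts the lists with fewer summits fell from 10 to 1, and histones (4.94%), collagens (3.39%), intestine (7.50%), body-wall muscle (6.67%), nuclear hormone receptors (4.74%), bHLH factors (7.32%) and detoxification enzymes (4.26%) reversed, because shifts put most summits outside promoters and so lower the chance share to a median of 2.78%. Uncalled values that crossed their reference, cause not tested, were pharynx markers (7.69% with narrow promoters, 13.2% with wide ones, 7.69% to 12.1% without a replicate), heterochronic genes (7.14% with narrow promoters, 27.3% against genes with a pooled-list entry), rRNA genes (0.929 to 1.17-fold without a replicate, 0 without mitochondrial peaks) and chromosome IV (0.979 to 1.02-fold without a replicate, 1.00 without mitochondrial peaks). Chromosome II reversed to 1.01-fold against chromosome length, its call lost; the cause was not tested. The 6-mers higher at summits numbered 630, and 581 with equal positions, all 581 among the 630, so the unequal positions added 49 calls; the 10 leading 6-mers were called under every alternative that tests 6-mers, which the 8-mer alternative does not. Depth is unknown, so no limit from it can be given, and chance for the 50% overlap was taken from 1 bp overlap, which is higher.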

Other observations

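Of the tests in this part, the background of genes with a pooled-list entry, the signal windows and merged peaks around W03F9.2, the count of summits at GCGCAGGG, and the comparisons of X with the autosomes and of shared summits were chosen after the values they bear on had been seen.

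Several of the strongest summits outside promoters lay on X. An intergenic peak at 12362983 to 12363325 had a signal of 342 and ranked 32, and an intronic one at 2996962 to 2997235 had a signal of 313. The sequence GCGCAGGG, part of the MEX motif of sites that recruit the dosage compensation complex to X, lay within 50 bp of 11 of 305 summits on X and 1 of 2084 on the autosomes (Fisher's exact test, odds ratio 77.9, p = 1.33e-09). How often the sequence occurs away from summits on X and on autosomes was not counted. A preference of the peaks for it therefore cannot be told apart from its own abundance on X. One of the 11, chosen after its value was seen, is intergenic at 8036318 to 8036514. The nearest protein-coding start is that of xol-1, a switch gene of sex determination, with the summit far upstream, at -4890. The same summit lies within 500 bp of a tRNA gene. Whether this peak bears on xol-1 was not tested. Of the 142 summits near tRNA genes, 71 (50%) lay on X, 58 on the autosomes and the rest on the mitochondrial genome. X holds 276 of the 634 annotated tRNA genes (43.5%), a difference from the 50% that was not tested. Summits near tRNA genes made up 23.3% of those on X and 2.78% of those on the autosomes (Fisher's exact test, odds ratio 10.6, p = 7.29e-33). That test does not allow for the number of tRNA genes on X. Of these 142 summits, 44 were in promoters, 58 intergenic, 37 in introns and 3 in exons.

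Longer words at summits fell into families. GCGCCAGC was at 83 summits and in no flank, GCGCTCCA at 102 summits and 2 flanks, GCGAGACC at 127 and 6, and GCAAACAC at 156 and 16, out of 2408. Members of the lower lists with a summit shared it with another gene in 27 of 49 cases (55.1%), and members of the higher lists in 201 of 317 (63.4%), a difference that did not pass Fisher's exact test (p = 0.272).

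The 11 higher lists together held 654 genes, 48.5% with a promoter summit against 10.4% of other genes (odds ratio 8.09). Their promoters had a median GC of 36.3% against 34.9%. Over 10 classes of promoter GC the common odds ratio was 7.39 (95% interval 6.27 to 8.70). This argues against GC content of the whole promoter window as the whole cause. GC content close to the summits was not stratified. The 11 lists were chosen for their odds ratios in these same data, which the interval does not allow for. Among genes with a pooled-list entry in the promoter the odds ratio was 4.36 (3.62 to 5.24), lower but above 1. Such entries come from the same ChIP, so they measure general openness only roughly and could also be weaker binding of the protein. Whether promoters that are open in general account for part therefore stays open. No control or second factor was analysed here that could decide it. No biological explanation was tested, since the design has 1 group.

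For the cluster around W03F9.2, the density of promoters of any kind is argued against. Of 1565 windows of the same length on chromosome V with as large a promoter share, 0 held 8 summits, and the highest held 7. These windows overlap each other, so they are not separate comparisons. They were matched on promoters of every gene group, so a local run of promoters of the groups that often carry summits is not excluded. With overlapping peaks merged the region held 6, as many as or fewer than 2 of the 1565 windows (0.128%). Extra template from the transgene may account for it, since it would raise places outside promoters too. The median signal there was 11.01 in replicate 1 and 17.4 in replicate 2, and 7.66% and 2.09% of other windows were as high, so replicate 1 missed the 5% set for this test. As written, the test then counted against extra template, and it was left undecided only after this outcome was seen. Added weak entries could lower a median, but whether they did so here was not tested. Replicate 1 had 31 entries outside promoters in the region and replicate 2 had 25, against a median of 7 per window. As many were held by 0 of 1592 other windows in replicate 1 and by 14 of 1436 in replicate 2. Extra template and binding of the protein to its own gene cannot be told apart, with the replicates on either side of the bound and no strain without the transgene among the samples.

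For the lower promoter share on X, removing summits within 500 bp of tRNA genes raised it from 47.5% to 56.4% (exact 95% interval 49.8 to 62.9), still below the lowest autosomal share of 71.1% on IV. This argues against them as the whole cause. Only 9 summits on X at GCGCAGGG lay outside promoters, and at least 77 such summits would have to be left out for the interval to reach the lowest autosomal share of 69.8%, so they are too few to account for it. Only exact copies of this sequence were counted, so other sites that recruit the dosage compensation complex are not covered. The share on X was 2.72 times its circular-shift chance (2.39 to 3.05), and the lowest autosomal ratio was 2.88 on V, so a lower density of promoters on X cannot be told apart from a preference for other places, because the interval reaches the ratio of V. Without summits near tRNA genes the ratio on X was 3.22, above those of V (2.90) and II (3.11), so a lower promoter density together with these summits also stays open. No biological explanation was tested.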
